A study of Homo sapiens with 12 samples.

How the data were processed

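Total RNA from the pancreatic ductal adenocarcinoma lines AsPC1 and BxPC3 and from 1 derivative of each with resistance to cisplatin (AsPC1-R, BxPC3-R), 3 arrays per group, was amplified, labelled and hybridized to Affymetrix arrays by the authors. The deposited values are log2 expression levels per probe set. The submitters' processing notes name Affymetrix Expression Console and RMA, which corrects background, quantile-normalizes the arrays and summarises probes, and the log2 scale was checked from the range of the values. Versions, the annotation release and the genome build behind the probe sets are not given in the sources used here. All 12 columns of values were matched to samples by their labels, and groups followed the labels. Array medians were near equal, as quantile normalization leaves them, so the deposited values hold no measure of depth, and the number of arrays limits the precision.

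The table holds 33297 probe sets. Those with 1 gene symbol, 19460, were kept, and the 1754 with several symbols and the 12083 not listed in the probe table were left out. For the 769 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which gave 18417 genes. Of these, 18389 were found by gene number in the RefSeq annotation of the GRCh38.p14 assembly, which was used only for the chromosome and the order of neighbouring genes. Genes whose highest group mean reached 6.554 (log2), the median of all values, were called expressed, 12328 in all. No gene was filtered out before testing.

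Changes were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 12 arrays and a mean for each of the 4 groups, which left 8 residual and 5.47 prior degrees of freedom. The contrasts were AsPC1-R minus AsPC1, BxPC3-R minus BxPC3, the first minus the second (the difference between the lines), and AsPC1 minus BxPC3. All tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the 18417 genes, and a gene was said to rise, fall or differ at an adjusted p under 0.05, with the genes changed at least 2-fold counted beside. A value in parentheses after a log2 change is its standard error from limma, with 3 arrays per group. The overlap of both derivatives was set beside the number that independent lists of the same sizes would share.

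Gene lists were tested with camera from limma, two-sided, with its preset correlation between genes of 0.01, and p-values were adjusted over the 34 lists. As an alternative, camera estimated the correlation for each list. Adjusted p values rose even where the estimate lay near the preset, as for YAP and TEAD targets in BxPC3-R (estimate 0.012, from 0.0291 to 0.150). A call lost with this setting is therefore not shown to be lost through correlation between genes. The lists cover platinum and copper transport, DNA repair, redox and stress responses, interferon and inflammation, proliferation, ribosomal proteins, metabolism, receptors and signalling targets, the classical and basal-like subtypes of pancreatic ductal adenocarcinoma, cell state, and markers of endothelium, fibroblasts, leukocytes and normal pancreas. Of 836 memberships, 749 were measured. Counts of members are given over all genes and adjusted over the list alone. Camera was also run on 369 windows of 50 neighbouring genes, with windows of 25 as an alternative.

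The lists, the contrasts and their tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls of each derivative, leaving out uncharacterised loci, small RNAs, antibody or receptor segments, XIST and Y-linked genes. It also took up to 4 members of each list with the largest called change, all called platinum transport genes with SLC31A1, ATP7A, ATP7B, ABCC2 and ERCC1 in any case, and up to 10 genes per direction changed at least 2-fold in both derivatives. The 5 largest differences between the lines per direction, the 6 largest between the parental lines per direction, SMAD4 and CDKN2A, and up to 3 genes of the 3 windows with the smallest adjusted p completed it. The text names some of them. The alternatives were replicate number as a block, dim genes left out, quantile normalization once more, arrays centred on their medians, eBayes with trend and robust, only the groups compared, the mean over probe sets, array weights, a test against a 1.5-fold change, an adjusted p under 0.01, and each array left out in turn.

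The pipeline was tested on simulated data with the spread that limma fitted for each gene. Of genes given a log2 change of 0.585, 82.1% were called in AsPC1-R, 86.7% in BxPC3-R, 39.0% for the difference between the lines and 80.0% between the parental lines. At a log2 change of 1 these shares were 100%, 97.5%, 88.9% and 100%, and of unchanged genes 0.093% or fewer were called. Each simulation left 18217 of the 18417 genes unchanged, while 3730 or more genes were called in each real contrast. The threshold on adjusted p depends on how many genes change, so these shares need not hold for the real data. Camera passed 5 of 5 shifted lists and 0 of 25 unshifted lists. The simulated genes varied independently of each other, so this does not give the rate of false passes for the real lists. There, other groupings of the arrays still passed 6 to 15 lists in the AsPC1 line and 4 to 13 in the BxPC3 line. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.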

Results

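Gene expression was measured on Affymetrix arrays in human pancreatic ductal adenocarcinoma cell lines. The 12 arrays fall into 4 groups of 3: the parental lines AsPC1 and BxPC3, and their derivatives resistant to cisplatin, AsPC1-R and BxPC3-R. Cisplatin is a platinum drug that crosslinks DNA. AsPC1-R was kept in 1.67 µM and BxPC3-R in 0.60 µM cisplatin, and the drug was left out for the last passage before RNA was taken. Levels are log2 values, the array medians over all probe sets lay between 6.48 and 6.65, and the number of arrays limits the precision. Background was not measured. SMAD4 and CDKN2A, which are deleted in BxPC3, read 4.70 and 6.22 there, so changes to, from or within levels up to 6.22 are uncertain in size. The labels do not say that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which can be technical. With 1 derivative per line, a change from the parental line is not shown to go with resistance rather than with that derivative. SMAD4, which is deleted in BxPC3, read 9.90 ± 0.14 in AsPC1 and 9.66 ± 0.14 in AsPC1-R, against 4.70 ± 0.49 in BxPC3 and 4.63 ± 0.18 in BxPC3-R (mean ± SD, n = 3). CDKN2A, also deleted in BxPC3, read 7.44 ± 0.25 and 7.67 ± 0.10 against 6.22 ± 0.11 and 5.75 ± 0.24 in the same order. BxPC3 replicate 2 stood apart in a check chosen after the values were seen: all 50 transcripts with the largest excess of AsPC1 over BxPC3-R were highest on that array among the 3 BxPC3 arrays, by a median of 0.83 over the mean of the other arrays. CDH17, for example, read 9.0 there and 4.99 and 4.47 on the other BxPC3 arrays, against a mean of 13.28 in AsPC1.

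The first comparison asked how AsPC1-R differs from AsPC1. The acute-phase gene SAA2 rose in AsPC1-R, from 5.41 ± 0.47 to 11.73 ± 0.15 (mean ± SD, n = 3; log2 change 6.33, SE 0.17). SAA1 rose by 4.80 (SE 0.25), the interferon-inducible SLFN5 by 4.85 (0.12), the MHC class II gene HLA-DPA1 by 4.75 (0.10), KYNU of tryptophan breakdown by 4.12 (0.10), and the chemokine genes CXCL5, CXCL10 and CXCL11 by 4.07 (0.10), 3.99 (0.20) and 3.72 (0.17). The complement gene C3 rose by 3.75 (0.14) and SCEL of the cornified envelope by 3.96 (0.12). Among the falls, the fatty acid binding protein gene FABP4 stood at -3.41 (SE 0.30), but its size is uncertain, since the level in AsPC1-R, 2.97, lies under that of the deleted SMAD4 in BxPC3. Other falls were those of the intestinal antigen gene GPA33 at -2.16 (0.16), the transcription factor gene MYB at -1.91 (0.11), the brush border myosin gene MYO1A at -1.64 (0.24) and the fatty acid transporter gene CD36 at -1.58 (0.14). CD36 read 5.63 in AsPC1 and 4.05 in AsPC1-R, both under the 6.22 of the deleted CDKN2A in BxPC3. Its fall is therefore not shown to stand above background. In AsPC1, SAA1, SAA2, HLA-DPA1, CXCL10, CXCL11, C3 and SCEL read 3.69 to 5.87, also under 6.22, so the sizes of their rises are uncertain. SAA2 is measured by 2 probe sets that differ in size, 6.33 for probe set 8180303 and 2.39 for probe set 7946983, and SAA1 and SAA2 are near-identical in sequence, so their separate sizes are uncertain. Of the 18417 genes tested, 3730 changed by limma at an adjusted p under 0.05, 2138 up and 1592 down, and 429 of them changed at least 2-fold, 348 up and 81 down. All 3 AsPC1-R arrays lay on 1 side of all 3 AsPC1 arrays for 33.4% of the tested genes, where chance gives 10%.

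Genes of the interferon and inflammatory lists rose together in AsPC1-R. Of 39 interferon-stimulated genes, 34 rose and 0 fell (34 and 0 adjusted over the list alone), with a median change of 0.89, among them IFI44L at 2.33 (SE 0.15), SAMD9L at 2.18 (0.08), IFIT2 at 2.17 (0.12) and IFI27 at 2.14 (0.12). The list passed camera, limma's test of a list against all other genes (adjusted p = 6.16e-31, adjusted p = 0.00415 with an estimated correlation). Of 32 NF-kB and inflammatory cytokine genes, 21 rose and 1 fell (23 and 2 adjusted over the list alone), led by SAA2, SAA1, CXCL5 and C3 (adjusted p = 6.66e-19, adjusted p = 0.00354 with an estimated correlation). In antigen presentation, 9 of 15 genes rose and 0 fell (10 and 0 adjusted over the list alone), among them HLA-DPB1 at 1.66 (0.18), with 0.83 and 1.82 on its other probe sets, HLA-DMA at 1.07 (0.17) and the immunoproteasome gene PSMB9 at 1.01 (0.17). Camera gave an adjusted p of 1.90e-07 and 0.0118 with an estimated correlation. Apoptosis regulators counted 9 rises and 2 falls among 29 genes (9 and 2 adjusted over the list alone), with PMAIP1 at 1.13 (0.08) and the death ligand gene TNFSF10 at 1.01 (0.11). For the list, camera's adjusted p was 0.00765 but 0.121 with an estimated correlation.

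NRF2 targets also rose in AsPC1-R. Of 25 NRF2 targets, 19 rose and 0 fell (20 and 0 adjusted over the list alone), with a median change of 0.62: the aldo-keto reductase genes AKR1B10 at 3.14 (SE 0.17) and AKR1C2 at 1.53 (0.15), the malic enzyme gene ME1 at 1.68 (0.09) and the aldehyde dehydrogenase gene ALDH3A1 at 1.35 (0.11). The adjusted p by camera was 1.65e-16 and 0.00507 with an estimated correlation. In glutathione and thioredoxin metabolism, 6 of 34 genes rose and 2 fell (6 and 2 adjusted over the list alone), among the rises GCLM at 1.15 (0.09), GPX2 at 1.08 (0.07), GCLC at 0.93 (0.08) and the cystine transporter gene SLC7A11 at 1.12 (0.09). That list passed with the preset correlation alone (adjusted p = 0.0312, adjusted p = 0.467 with an estimated correlation) and not without AsPC1 replicate 2 (adjusted p = 0.211) or AsPC1-R replicate 2 (adjusted p = 0.130). Of 18 platinum and copper transport genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone). By camera, the list's adjusted p was 0.00112 but 0.0951 with an estimated correlation. The exporter genes ABCC4, ABCC3 and ABCC2 rose by 1.30 (0.10), 0.69 (0.09) and 0.64 (0.14), the copper transporter genes SLC31A2, ATP7A and SLC31A1 by 0.64 (0.12), 0.42 (0.10) and 0.39 (0.08). TMEM205, ATOX1, ABCC5 and LRRC8D rose by 0.56 (0.14), 0.36 (0.12), 0.32 (0.10) and 0.31 (0.09), and ABCC1 fell by 0.34 (0.09). These last 5 calls were lost with single arrays left out, with adjusted p values of 0.0626, 0.192, 0.161 and 0.0851 for TMEM205, ATOX1, ABCC5 and ABCC1 without AsPC1-R replicate 2 and of 0.0932 for LRRC8D without AsPC1-R replicate 1. ATP7B changed by 0.28 (0.11) with an adjusted p of 0.104, and the excision repair gene ERCC1 by 0.28 (0.12) with an adjusted p of 0.104, or of 0.0411 without AsPC1-R replicate 3.

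Genes of cell division and some of sterol synthesis fell in AsPC1-R. Of 33 mitosis genes, 23 fell and 0 rose (26 and 0 adjusted over the list alone), with a median change of -0.53, among them the kinetochore genes NUF2 at -0.87 (SE 0.09), CENPE at -0.86 (0.10) and CENPF at -0.77 (0.08). The list had a camera adjusted p of 3.47e-15 and 0.00354 with an estimated correlation. DNA replication did not move as a list: 1 of 37 genes, CDC6 at 0.54 (0.08), rose and 4 fell (1 and 2 adjusted over the list alone; adjusted p = 0.896). Of 20 cholesterol synthesis genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone): STARD4 at -1.28 (0.11), INSIG1 at -0.78 (0.08), the transcription factor gene SREBF2 at -0.74 (0.09) and MSMO1 at -0.65 (0.10). Tested as a list, it had an adjusted p of 1.25e-05 and 0.00507 with an estimated correlation. Of 10 metallothionein genes, which encode metal-binding proteins, 4 fell and 0 rose (6 and 0 adjusted over the list alone), with MT1E at -0.90 (0.10) and MT2A at -0.57 (0.08), or -1.54 on its probe set 7995783 (adjusted p = 0.00112, adjusted p = 0.0192 with an estimated correlation). Immediate early and heat shock genes, which respond to handling, counted 1 rise and 7 falls among 19 (1 and 7 adjusted over the list alone), with EGR1 at -1.13 (0.13) and FOS at -0.99 (0.11). Their list passed (adjusted p = 0.0263, adjusted p = 0.272 with an estimated correlation), but not without AsPC1 replicate 1 (adjusted p = 0.0589).

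Lists of cell state moved in AsPC1-R as well. Among 19 genes of the basal-like subtype of pancreatic cancer, 9 rose and 0 fell (9 and 0 adjusted over the list alone), including SCEL, the long noncoding RNA gene UCA1 at 2.50 (SE 0.18) and FAM83A at 1.40 (0.08). Camera gave an adjusted p of 2.54e-06 and 0.00497 with an estimated correlation. Among 23 genes of the classical subtype, 7 fell and 1 rose (7 and 1 adjusted over the list alone), including MYO1A, REG4 at -1.25 (0.15) and AGR2 at -0.99 (0.11). For the list, camera's adjusted p was 0.00837 but 0.151 with an estimated correlation. Of 29 epithelial genes, 10 fell and 2 rose (15 and 2 adjusted over the list alone), with CDS1 at -0.94 (0.11) and the tight junction gene CLDN7 at -0.68 (0.09), and with MAL2 rising by 1.79 (0.11). The adjusted p by camera was 0.00102 and 0.0188 with an estimated correlation. Of 22 YAP and TEAD targets, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with ANKRD1 at 3.58 (0.12) and TGFB2 at 2.28 (0.10). By camera, the list's adjusted p was 4.16e-05 and 0.0116 with an estimated correlation. Of 25 p53 targets, 9 rose and 3 fell (11 and 3 adjusted over the list alone), with PLK2 at 0.96 (0.08) and CDKN1A at 0.51 (0.11). The list had a camera adjusted p of 0.00837 and 0.0358 with an estimated correlation. Stem cell markers rose in 6 of 15 cases and fell in 0 (6 and 1 adjusted over the list alone), with CD24 at 2.75 (0.12) and ALDH1A1 at 1.24 (0.29). Tested as a list, it had an adjusted p of 0.0268, 0.121 with an estimated correlation, and 0.0696 without AsPC1 replicate 3. WNT targets rose in 1 of 15 cases and fell in 5 (1 and 6 adjusted over the list alone), with DKK1 at -0.69 (0.10). Camera gave an adjusted p of 0.0488 and 0.163 with an estimated correlation. The WNT call was lost without AsPC1 replicate 1 (adjusted p = 0.104), AsPC1-R replicate 2 (0.0830) or BxPC3-R replicate 3 (0.0505).

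The other lists did not pass camera in AsPC1-R. Rises and falls, with those adjusted over the list alone in brackets and camera's adjusted p last, were 6 and 1 of 35 genes for the amino acid and ER stress response [6 and 1] at 0.0908, and 7 and 2 of 21 for ERBB receptors and ligands [7 and 4] at 0.179. There were 3 and 4 of 29 for Fanconi anaemia and homologous recombination [3 and 4] at 0.696, and 7 and 2 of 29 for hypoxia and glycolysis [8 and 4] at 0.0718. They were 7 and 2 of 31 for mesenchymal genes [7 and 2] at 0.210, 0 and 1 of 6 for mismatch repair [0 and 1] at 0.567, 1 and 1 of 10 for mucins [1 and 1] at 0.586. Counts were 3 and 1 of 23 for nucleotide excision repair [5 and 1] at 0.0908, and 1 and 2 of 31 for ribosomal proteins [0 and 0] at 0.567. Squamous differentiation had 1 and 3 of 28 [1 and 3] at 0.696, where the rise was that of the elastase inhibitor gene PI3 at 3.64 (SE 0.12), and translesion synthesis 1 and 2 of 11 [2 and 3] at 0.896. Markers of other cell types gave 1 and 0 of 8 for endothelium [1 and 0] at 0.928, 0 and 1 of 10 for fibroblasts [0 and 1] at 0.236, 3 and 0 of 11 for leukocytes [3 and 0] at 0.341, and 0 and 1 of 7 for pancreatic acinar and endocrine cells [0 and 0] at 0.477. Single arrays decided 4 of these: without AsPC1 replicate 3, the amino acid and ER stress, hypoxia, and excision repair lists passed (adjusted p = 0.0246, 0.0204 and 0.0204), and without AsPC1 replicate 2 the ribosomal proteins did (0.0228). Hypoxia also passed without AsPC1 replicate 1 (0.0463) or AsPC1-R replicate 1 (0.0482), and excision repair without AsPC1-R replicate 3 (0.0408). With dim genes left out, the apoptosis, glutathione, p53 and stem cell lists did not pass in AsPC1-R (0.050, 0.0930, 0.0574 and 0.0715). Camera's direction, the median and the mean differed in sign for DNA replication (up, -0.007 and -0.004), squamous differentiation (down, -0.114 and 0.020), mesenchymal genes (up, -0.045 and 0.163), endothelial markers (down, -0.054 and 0.005) and leukocyte markers (up, -0.052 and 0.104).

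**Figure D1:**
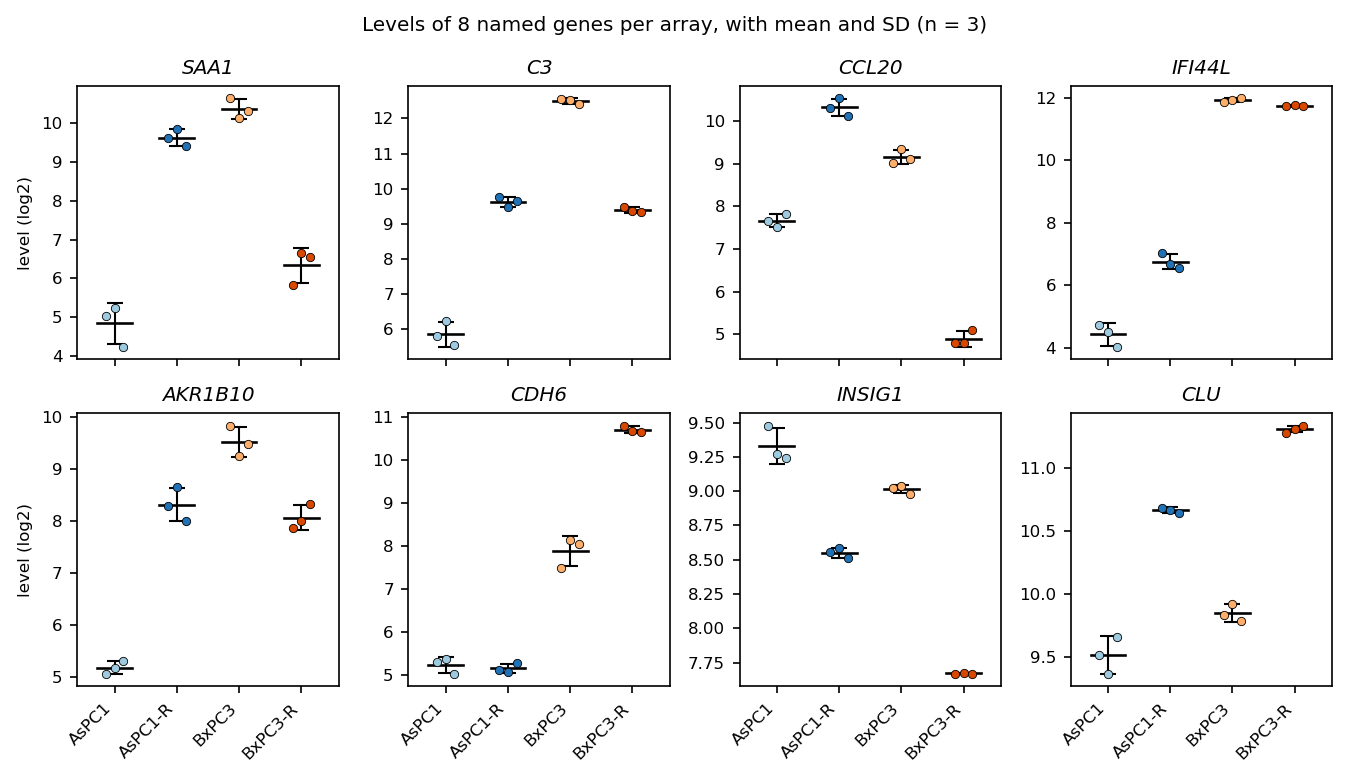
Levels of 8 genes on each array (dots) in the 4 groups, with the group mean (bar) and SD (error bar, n = 3), on the log2 scale. SAA1, C3 and CCL20 stand higher in AsPC1-R than in AsPC1 and lower in BxPC3-R than in BxPC3, while INSIG1 stands lower in both derivatives.

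The second comparison asked how BxPC3-R differs from BxPC3. Inflammatory genes fell: TNIP3, an inhibitor of NF-kB, from 9.18 ± 0.13 to 4.85 ± 0.34 (mean ± SD, n = 3; log2 change -4.33, SE 0.14), and the chemokine gene CCL20 from 9.16 ± 0.17 to 4.89 ± 0.18 (-4.27, SE 0.13). Both ended near the 4.63 of the deleted SMAD4 in BxPC3-R, so the sizes of their falls are uncertain. SAA1 stood at -4.04 (0.25), SAA2 at -3.99 (0.17), or -2.96 on its other probe set, the NADPH oxidase gene DUOX2 at -3.70 (0.08), the pantetheinase gene VNN1 at -3.66 (0.20), the calgranulin gene S100A8 at -3.30 (0.19), and the complement genes C1S and C3 at -3.21 (0.17) and -3.09 (0.14). VNN1 and S100A8 ended at 4.9 and 5.95, under the 6.22 of the deleted CDKN2A in BxPC3, so their sizes are uncertain too. Among the rises were the cadherin gene CDH6 at 2.82 (0.15), the regulator of G-protein signalling RGS4 at 2.67 (0.21), RERG at 2.57 (0.15), the hyaluronan synthase gene HAS2 at 2.53 (0.18), SYTL5 at 2.38 (0.08) and the insulin-like growth factor binding protein gene IGFBP5 at 2.05 (0.10). RGS4 and RERG rose from 6.2 and 5.41 in BxPC3, also under 6.22, which leaves the sizes of these rises uncertain. With limma, 3826 genes changed, 1795 up and 2031 down, and 428 of them at least 2-fold, 110 up and 318 down. Rises made up 46.9% of the changed genes, but 56.7% when arrays were centred on their medians, so which direction prevailed depends on the scaling. All 3 BxPC3-R arrays lay on 1 side of all 3 BxPC3 arrays for 38.2% of the tested genes, where chance gives 10%. BxPC3 replicate 2, whose AsPC1-type transcripts stood high, entered this comparison; without it 3203 genes changed, 1601 up and 1602 down, and 434 at least 2-fold, 138 up and 296 down. CDH17 stood at -1.95 with that array and at -0.53 without it, LYZ at -0.89 and 0.12, VNN1 at -3.66 and -3.33, and VIM at 2.02 and 2.43.

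Inflammatory genes and NRF2 targets fell in BxPC3-R. Of 32 NF-kB and inflammatory cytokine genes, 26 fell and 0 rose (28 and 0 adjusted over the list alone), with a median change of -1.02 (adjusted p = 4.87e-28, adjusted p = 0.00156 with an estimated correlation). Of 39 interferon-stimulated genes, 17 fell and 0 rose (19 and 0 adjusted over the list alone), with a median change of -0.23, among them IFITM1 at -1.92 (SE 0.10), IFI27 at -1.89 (0.12) and TRIM22 at -1.82 (0.14). For the list, camera's adjusted p was 7.83e-09 but 0.0786 with an estimated correlation. In antigen presentation, 10 of 15 genes fell and 0 rose (10 and 0 adjusted over the list alone), among them PSMB9 at -1.42 (0.17), PSMB8 at -1.17 (0.22) and the MHC class I light chain gene B2M at -0.79 (0.12). The adjusted p by camera was 7.89e-06 and 0.0395 with an estimated correlation. Of 25 NRF2 targets, 18 fell and 0 rose (19 and 1 adjusted over the list alone), with AKR1C1 at -1.99 (0.13) or -0.62 on its other probe set, AKR1C2 at -1.96 (0.15) and ALDH3A1 at -1.71 (0.11). By camera, the list's adjusted p was 1.82e-12 and 0.0220 with an estimated correlation. In glutathione and thioredoxin metabolism, 14 of 34 genes fell and 0 rose (16 and 2 adjusted over the list alone), with GCLC at -1.14 (0.08) and TXNIP at -0.97 (0.10). The list had a camera adjusted p of 2.28e-05 but 0.158 with an estimated correlation. The amino acid and ER stress list had 13 falls and 1 rise among 35 genes (17 and 3 adjusted over the list alone), with SLC7A11 at -0.91 (0.09) and XBP1 at -0.72 (0.08). Tested as a list, it had an adjusted p of 0.000233 but 0.0870 with an estimated correlation. Of 29 apoptosis regulators, 9 fell and 3 rose (9 and 3 adjusted over the list alone), with TNFSF10 at -1.50 (0.11) and the caspase-8 inhibitor gene CFLAR at -1.38 (0.09), or -0.66 on its other probe set. Camera gave an adjusted p of 0.00591 but 0.154 with an estimated correlation.

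Some sterol synthesis and metallothionein genes fell in BxPC3-R too, and some replication genes rose. Of 20 cholesterol synthesis genes, 11 fell and 1 rose (11 and 2 adjusted over the list alone), with INSIG1 at -1.34 (SE 0.08), SREBF2 at -0.97 (0.09), MSMO1 at -0.94 (0.10) and DHCR7 at -0.91 (0.10). For the list, camera's adjusted p was 9.29e-06 and 0.0135 with an estimated correlation. Of 10 metallothionein genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone), with MT1E at -1.01 (0.10), MT1X at -0.53 (0.12) and MT2A at -0.48 (0.08). The adjusted p by camera was 0.000641 and 0.0387 with an estimated correlation. Of 37 DNA replication genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone), with the origin recognition gene ORC1 at 0.87 (0.15), the cyclin gene CCNE2 at 0.79 (0.09) and POLA1 at 0.71 (0.10). By camera, the list's adjusted p was 7.83e-09 but 0.169 with an estimated correlation. Of 29 Fanconi anaemia and homologous recombination genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone), with XRCC2 at 0.98 (0.13) and RAD51C at 0.51 (0.11). The list had a camera adjusted p of 0.00143 but 0.297 with an estimated correlation. Among 33 mitosis genes, 2 rose and 4 fell (3 and 6 adjusted over the list alone), with FOXM1 at 0.51 (0.11) and HMMR at -0.41 (0.09), and the list did not pass (adjusted p = 0.362). Nor did platinum and copper transport, with 2 rises and 4 falls among 18 genes (2 and 4 adjusted over the list alone; adjusted p = 0.362). ATP7A rose by 0.71 (0.10) and ABCC4 by 0.31 (0.10), ABCC3 stood at -0.96 (0.09), SLC31A2 at -0.45 (0.12), ABCC5 at -0.40 (0.10) and ATP7B at -0.38 (0.11), and SLC31A1 and ABCC2 changed by 0.16 (0.08) and 0.08 (0.14) with adjusted p values of 0.181 and 0.761. The calls of ABCC4, ABCC5, SLC31A2 and ATP7B were lost with single arrays left out, with adjusted p values of 0.156 without BxPC3-R replicate 3, 0.0596 and 0.0574 without BxPC3 replicate 2, and 0.146 without BxPC3-R replicate 1. Nucleotide excision repair had 5 rises and 1 fall among 23 genes (5 and 1 adjusted over the list alone; adjusted p = 0.187), with ERCC1 at 0.71 (0.12) and LIG1 at 0.58 (0.09).

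Of the cell state lists, mucins fell in 6 of 10 cases and rose in 0 (7 and 0 adjusted over the list alone), with MUC2 at -1.15 (SE 0.12) and MUC16 at -1.01 (0.12). Tested as a list, it had an adjusted p of 0.000306 but 0.0738 with an estimated correlation. MUC13 and MUC17 read higher on BxPC3 replicate 2 than on the other BxPC3 arrays and stood at -0.89 and -0.99 with that array and at -0.62 and -0.37 without it, where the list's adjusted p was 8.99e-05. Squamous differentiation counted 9 falls and 5 rises among 28 genes (10 and 6 adjusted over the list alone), with S100A8, the cornified envelope gene SPRR2A at -3.21 (0.14) and PI3 at -2.97 (0.12). Camera gave an adjusted p of 0.0204 but 0.358 with an estimated correlation. Among 8 endothelial markers, 3 fell and 0 rose (3 and 0 adjusted over the list alone): CDH5 at -2.67 (0.15), TEK at -1.71 (0.12) and PECAM1 at -1.24 (0.13), or -0.81 on its other probe set. For the list, camera's adjusted p was 0.00780 but 0.210 with an estimated correlation. Hypoxia and glycolysis fell in 9 of 29 cases and rose in 3 (10 and 3 adjusted over the list alone), with EGLN3 at -1.60 (0.13) and ALDOC at -1.24 (0.09). The adjusted p by camera was 0.0291, 0.358 with an estimated correlation, and 0.0539 without BxPC3 replicate 2 or 0.0838 without BxPC3-R replicate 2. YAP and TEAD targets fell in 7 of 22 cases and rose in 1 (8 and 1 adjusted over the list alone), with ANKRD1 at -1.26 (0.12) and CCN2 at -0.77 (0.11). By camera, the list's adjusted p was 0.0291, 0.150 with an estimated correlation, and 0.0683 without BxPC3 replicate 2 or 0.0539 without BxPC3-R replicate 2. WNT targets rose in 3 of 15 cases and fell in 1 (4 and 1 adjusted over the list alone), with BMP4 at 0.95 (0.16) and LEF1 at 0.82 (0.16). The list had a camera adjusted p of 0.0458 and 0.188 with an estimated correlation. The WNT call was lost without AsPC1-R replicate 2 (0.0509), BxPC3 replicate 3 (0.0843), BxPC3-R replicate 1 (0.0683) or BxPC3-R replicate 2 (0.0570). It was also lost when arrays were centred on their medians (0.0649), normalized once more (0.0575), fitted with replicate number as a block (0.0534), or analysed without dim genes (0.0533), where the YAP and TEAD list did not pass either (0.0533). The mesenchymal list did not pass, with 5 rises and 5 falls among 31 genes (7 and 5 adjusted over the list alone; adjusted p = 0.466). The intermediate filament gene VIM stood at 2.02 (0.26) and the cadherin gene CDH2 at 1.31 (0.14), and the smooth muscle actin gene ACTA2 at -1.41 (0.09) and the fibronectin gene FN1 at -1.34 (0.13).

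The remaining lists did not pass in BxPC3-R. Rises and falls, in the same form, were 4 and 7 of 19 genes for the basal-like subtype [4 and 8] at 0.201, 5 and 2 of 23 for the classical subtype [5 and 2] at 0.623. Next were 5 and 11 of 29 for epithelial genes [6 and 11] at 0.164, 6 and 2 of 21 for ERBB receptors and ligands [9 and 5] at 0.194, and 2 and 5 of 19 for immediate early and heat shock genes [3 and 7] at 0.243. They were 1 and 0 of 6 for mismatch repair [1 and 0] at 0.194, 2 and 7 of 25 for p53 targets [5 and 8] at 0.194. Counts were 4 and 0 of 31 for ribosomal proteins [4 and 0] at 0.220, 3 and 3 of 15 for stem cell markers [3 and 3] at 0.463, and 1 and 3 of 11 for translesion synthesis [1 and 3] at 0.669. Markers of other cell types gave 3 and 0 of 10 for fibroblasts [3 and 0] at 0.119, or 0.0371 without BxPC3-R replicate 3, 0 and 2 of 11 for leukocytes [1 and 2] at 0.194, and 0 and 0 of 7 for pancreatic acinar and endocrine cells [0 and 0] at 0.669. For the classical subtype camera's direction was up and the median 0.045, but the mean was -0.049. Camera passed 18 lists in AsPC1-R and 17 in BxPC3-R, of which 11 and 5 held with an estimated correlation. When the 6 arrays of a line were regrouped in the 9 other ways, camera with the preset correlation still passed 6 to 15 lists in the AsPC1 arrays and 4 to 13 in the BxPC3 arrays.

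**Figure D2:**
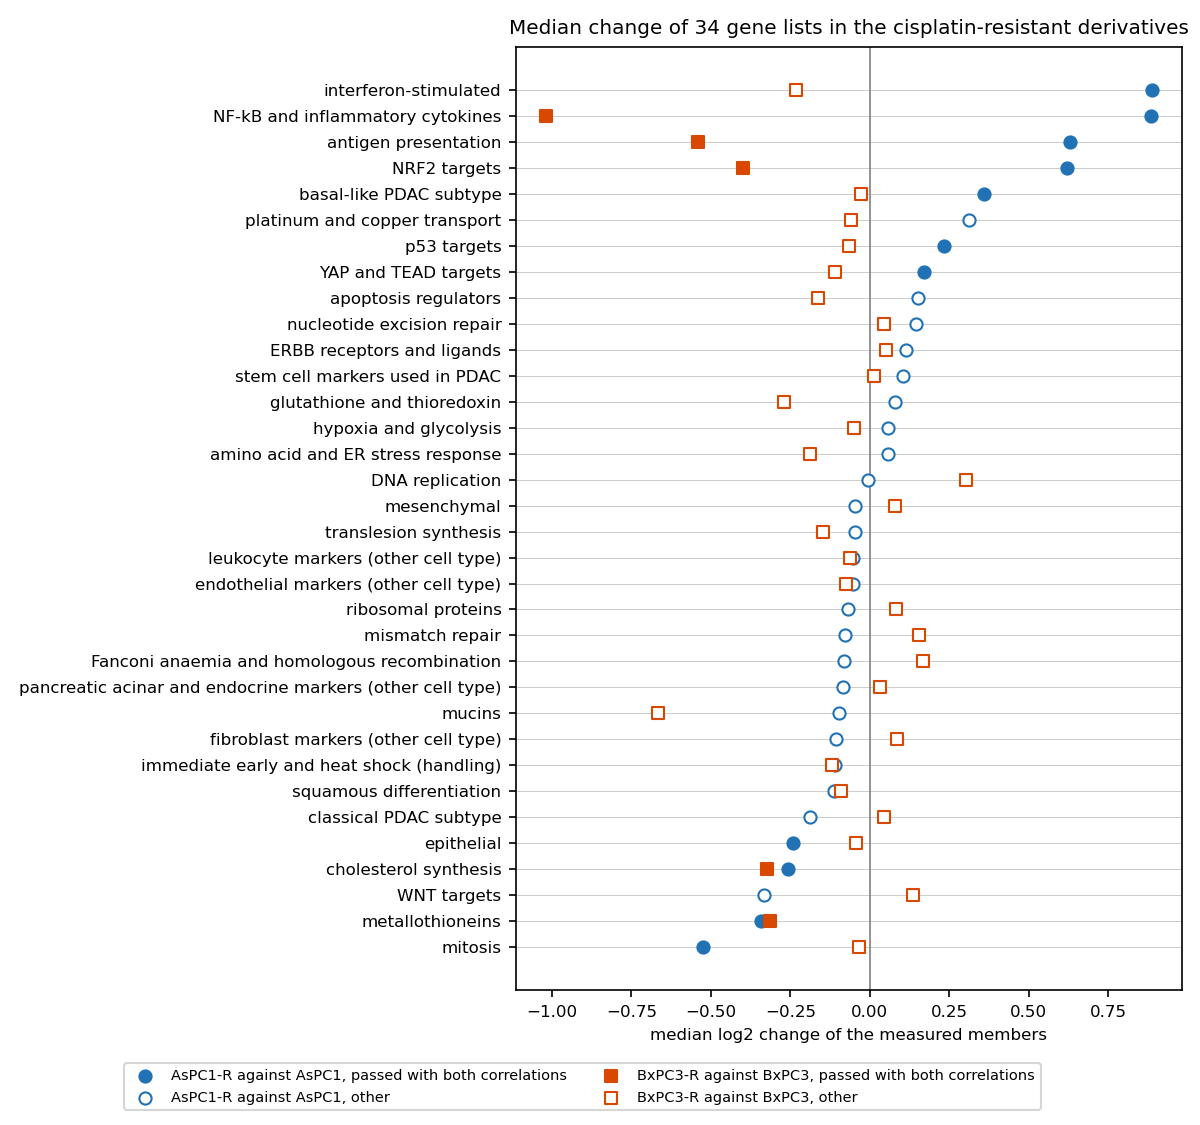
Median log2 change of the 34 gene lists in AsPC1-R against AsPC1 (circles) and in BxPC3-R against BxPC3 (squares), filled where camera's adjusted p was under 0.05 with an estimated correlation as well as with the preset one. NF-kB and inflammatory genes have medians of 0.89 and -1.02, and cholesterol synthesis of -0.26 and -0.32.

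The third comparison asked whether the derivatives differ from their parental lines in the same way. Inflammatory genes went in opposite directions: the change of SAA2 in AsPC1-R exceeded that in BxPC3-R by 10.31 (log2, SE 0.24, 3 arrays per group), or by 5.35 on its other probe set, that of SAA1 by 8.83 (0.36), CXCL5 by 7.12 (0.15), CCL20 by 6.93 (0.18) and C3 by 6.85 (0.20). The difference had the other sign for SYTL5 at -3.96 (0.11), HAS2 at -3.65 (0.25), FABP4 at -3.40 (0.42), CDH6 at -2.91 (0.21) and RGS4 at -2.76 (0.30). By limma's test of the difference, 4685 genes differed between the lines, 2595 with the higher change in AsPC1-R and 2090 with the lower, and 1157 differed at least 2-fold, 832 higher and 325 lower. The higher change in AsPC1-R was found for 55.4% of the differing genes, but for 44.4% when arrays were centred on their medians. With each array centred on its median, the share of higher calls was 44.4% against 55.4% as deposited, so the balance of directions over all genes depends on the scaling. Of the genes that changed in both derivatives, 991 went in opposite directions, 631 of them up in AsPC1-R and down in BxPC3-R and 360 the reverse, where independent lists would give 235.8 and 155.2. Another 435 went the same way, 233 up and 202 down, against 208.4 and 175.6 for independent lists. The numbers for independent lists take all 18417 tested genes as the background, dim ones included, and depend on that choice. The small excess in the same direction is therefore not shown to exceed chance. Without BxPC3 replicate 2, 4186 genes differed between the lines, 845 went in opposite directions and 374 the same way. Across genes, which are not independent replicates, the changes of the lines correlated at r = -0.255 and rho = -0.172.

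At 2-fold or more in both, 73 genes rose in AsPC1-R and fell in BxPC3-R and 7 did the reverse, against 6.0 and 0.5 for independent lists. Besides the inflammatory genes, the first set held PI3, the amino acid transporter gene SLC6A14 (3.13 and -2.61) and the cystatin gene CST1 (3.20 and -2.23), and the second held SYTL5, the prostaglandin-degrading enzyme gene HPGD (-1.39 and 1.35) and PAG1 (-1.10 and 1.28). The same way at 2-fold or more went 9 genes, 7 up and 2 down, against 2.1 and 1.4. The neural adhesion gene CNTN1 rose by 1.88 (SE 0.10) in AsPC1-R and 1.72 (0.10) in BxPC3-R, the chaperone gene CLU by 1.15 (0.09) and 1.46 (0.09), GPAT3 of glycerolipid synthesis by 1.38 (0.13) and 1.21 (0.13). The receptor gene ROR1 rose by 1.03 (0.19) and 1.16 (0.19), MAPRE2 by 1.01 (0.08) and 1.03 (0.08), IL1RAPL2 by 1.96 (0.19) and 1.17 (0.19), and the calponin gene CNN3 by 3.07 (0.09) and 1.07 (0.09). The stearoyl-CoA desaturase gene SCD stood at -1.36 (0.09) and -1.16 (0.09), and PECR at -1.0 (0.10) and -1.0 (0.10). Of these 9, IL1RAPL2 and CNN3 differed in size between the lines (limma adjusted p = 0.0457 and 4.24e-08). Of the lists, 19 differed between the lines and 7 of them held with an estimated correlation: NF-kB and inflammatory cytokines, interferon-stimulated genes, NRF2 targets, antigen presentation, the basal-like subtype, mitosis, and YAP and TEAD targets, with adjusted p values of 0.00171, 0.00570, 0.00570, 0.0101, 0.0126, 0.0126 and 0.0168 with an estimated correlation. Cholesterol synthesis and metallothioneins, lists that passed as lower in both derivatives, had median differences of 0.07 and -0.04 between the lines (camera adjusted p = 0.644 and 0.989).

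**Figure D3:**
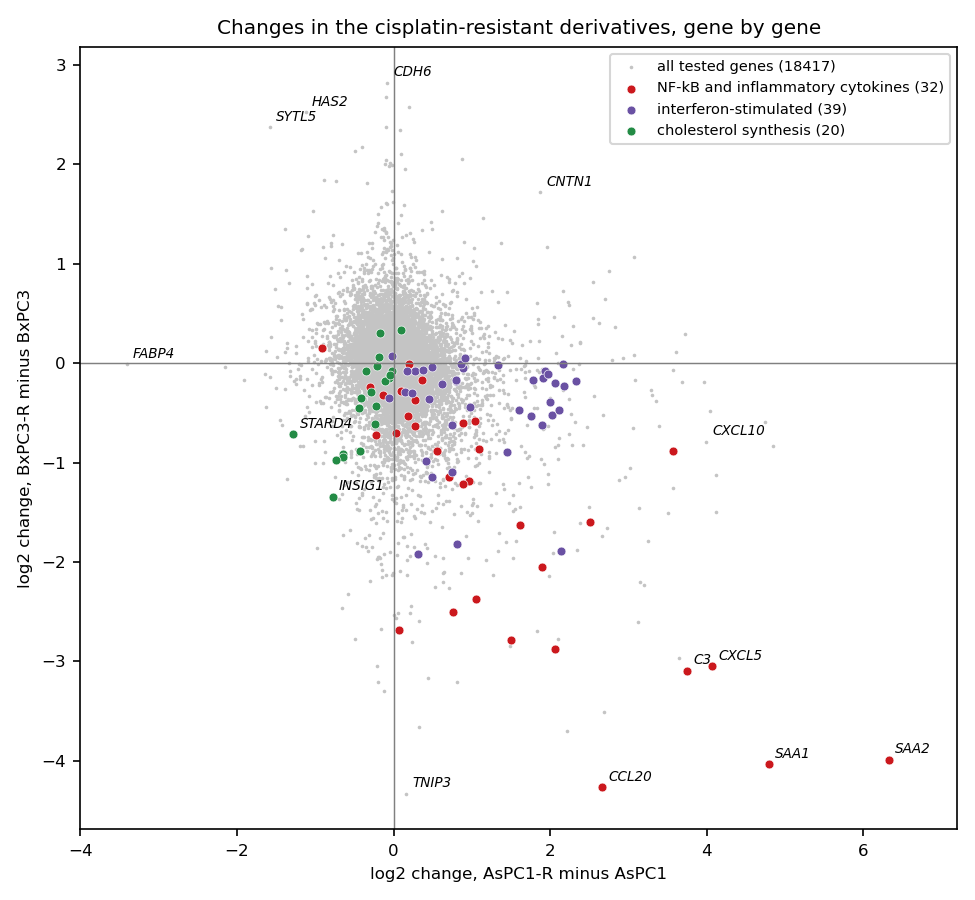
Log2 change of the 18417 tested genes in AsPC1-R against AsPC1 (x) and in BxPC3-R against BxPC3 (y), with members of 3 lists in colour. Inflammatory genes lie to the lower right, cholesterol synthesis genes to the lower left, and the correlation across all genes is -0.255.

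The fourth comparison set AsPC1 against BxPC3, the background of the other comparisons. AsPC1 stood above BxPC3 in the intestinal cadherin gene CDH17 by 7.12 (log2, SE 0.79), the WNT-responsive stem cell gene LGR5 by 6.75 (0.33), the mucin gene MUC17 by 6.74 (0.36), the proteoglycan gene LUM by 6.63 (0.22), the lysozyme gene LYZ by 6.52 (0.56) and ANXA13 by 6.52 (0.27). BxPC3 stood above AsPC1 in the lactate dehydrogenase gene LDHB at -8.44 (0.14), the lysyl hydroxylase gene PLOD2 at -7.99 (0.15), LCP1 at -7.76 (0.19), the interferon-stimulated gene IFI44L at -7.51 (0.15), FYB1 at -7.28 (0.18) and CXCL10 at -6.87 (0.20). With limma, 9316 genes differed, 5098 higher in AsPC1 and 4218 lower, and 2040 differed at least 2-fold, 746 higher and 1294 lower. The arrays of the groups did not overlap for 54.3% of the tested genes, where chance gives 10%. Without BxPC3 replicate 2, 7729 genes differed, 4002 higher and 3727 lower, and CDH17 and LYZ differed by 8.55 and 7.53.

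Neighbouring genes shifted together on some chromosomes. In BxPC3-R, 78.7% of the 654 expressed genes of chromosome 12 were higher than in BxPC3 (median 0.23) and 267 of them rose and 34 fell by limma. In AsPC1-R 69.6% were lower than in AsPC1 (median -0.13) and 182 fell and 65 rose. Chromosome 15 had a median of 0.21 in AsPC1-R, with 155 of 369 genes rising and 13 falling, and chromosome 17 a median of 0.14, with 268 of 750 rising and 26 falling. Of 369 windows of 50 neighbouring genes, camera passed 42 in AsPC1-R, 19 higher and 23 lower, and 39 in BxPC3-R, 33 higher and 6 lower. With an estimated correlation, 0 of the 369 windows passed in either line by camera, 42 and 39 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0680 and 0.275. With the preset correlation, the passing windows lay mostly on chromosomes 12 (10 lower), 17 (9 higher), 1 (8 lower) and 15 (7 higher) in AsPC1-R, and on 12 (14 higher), 1 (12 higher) and 19 (5 higher) in BxPC3-R. The smallest adjusted p with it in AsPC1-R, 2.77e-06, was that of the chromosome 17 window from GHDC to MPP2, where 79.5% of expressed genes were higher and STAT3 rose by 1.21 (SE 0.09). Next came the chromosome 15 window from LARP6 to SCAMP5 (0.000106), where HEXA rose by 1.98 (0.15), and, tied at 0.000267, the chromosome 12 window from PPP1R12A to USP44, where EEA1 and KITLG stood at -1.0 (0.09) and -0.71 (0.07), and the chromosome 17 window from PCTP to CHCT1. In BxPC3-R they were the chromosome 1 window from CDC7 to OLFM3 (3.06e-10), where 97.4% of expressed genes were higher and PALMD and GLMN rose by 1.18 (0.15) and 1.11 (0.10). Beside it were the chromosome 12 windows from DYRK2 to PAWR (1.76e-06), with PTPRR at 1.81 (0.11), and from ERP27 to MED21 (4.55e-06), with PIK3C2G at 2.37 (0.10).

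**Figure D4:**
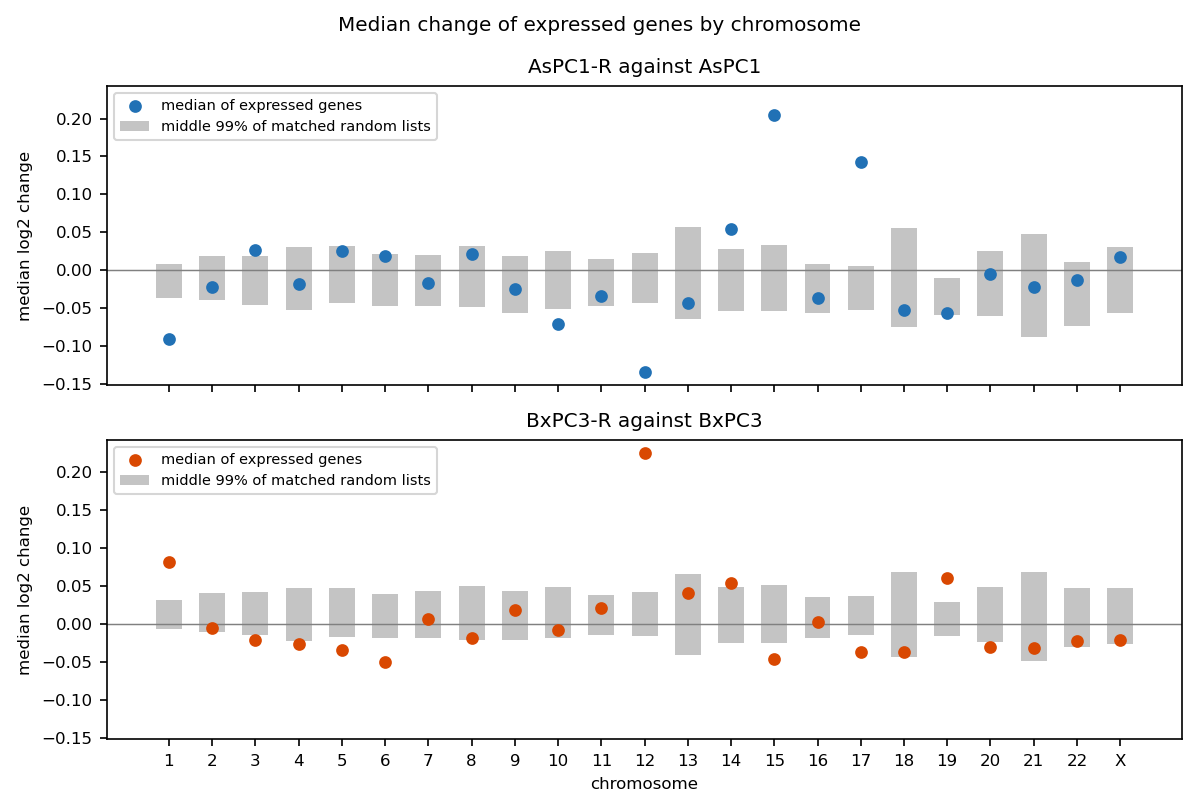
Median log2 change of the expressed genes of each chromosome in AsPC1-R against AsPC1 and in BxPC3-R against BxPC3 (dots), with the middle 99% of 10000 random lists of expressed genes matched in number and mean level (grey bars). Chromosome 12 lies below the bar at -0.13 in AsPC1-R and above it at 0.23 in BxPC3-R, and chromosomes 15 and 17 lie above it in AsPC1-R. In all, 7 of 23 chromosomes lie outside their bars in AsPC1-R and 11 of 23 in BxPC3-R.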

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

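The weighing of technical explanations here used tests chosen after the results were seen, while the comparisons with other groupings of the arrays were fixed in advance. The change in AsPC1-R differed from that in BxPC3-R for 4685 genes by limma's test of the difference, for 1157 of them at least 2-fold, and 991 genes changed in both derivatives in opposite directions. In 100 groupings of the arrays within each line, the real one included, 1 gave as many differing genes, and the highest other gave 1508. The other groupings mix derivative and parental arrays in 1 or both lines, since the draw did not leave out those that keep 1 line as labelled. So they do not all stand for no change in either line, and they do not stand for an equal change in both. They cannot show that the changes of the 4685 genes differ between the lines, and no conclusion on chance is drawn from them. Opposite changes (991) and changes in the same direction (435) were each as frequent in 1 of 100 groupings, the highest other giving 0 for both by limma. Since the other groupings of either line gave 0 genes, these counts could only be 0 there, and they add nothing to the comparison with 10 groupings below. The lists that differed numbered 19, and 1 of 100 groupings gave as many, though another gave 17. The derivatives' own counts can be set against 10 groupings of 6 arrays only, too few for a share under 0.05. The real grouping gave 3730 genes in AsPC1-R and 3826 in BxPC3-R, and for the parental lines 9316, each reached by 1 of 10 groupings, and the highest other gave 0 by limma in all 3 cases. At an unadjusted p under 0.05 the real counts were 5845, 5592 and 10520 and the highest others 2203, 1260 and 2592. For lists the real counts were 18 and 17 and the highest others 15 and 13, so camera with its preset correlation passed many lists where limma called 0 genes. For windows of neighbouring genes the real counts were 42 and 39 and the highest others 11 and 14.

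The lists singled out by camera's test of the difference had these median differences (log2, AsPC1-R change minus BxPC3-R change). Those that held with an estimated correlation were NF-kB and inflammatory cytokines 2.03, interferon-stimulated genes 1.63, antigen presentation 1.20, NRF2 targets 1.08, the basal-like subtype 0.53, mitosis -0.49, and YAP and TEAD targets 0.31. The others had medians of -0.44 for WNT targets, 0.41 for mucins, 0.30 for the amino acid and ER stress response, 0.29 for apoptosis regulators, -0.29 for DNA replication, -0.27 for Fanconi anaemia and homologous recombination, 0.24 for platinum and copper transport, 0.23 for glutathione and thioredoxin, -0.23 for the classical subtype, 0.13 for p53 targets, 0.08 for endothelial markers, and 0.00 for hypoxia and glycolysis. Their adjusted p values with an estimated correlation lay between 0.0889 and 0.433, and for hypoxia the median before rounding was -0.001 while camera's direction was up and the mean 0.368. Calls were lost for the classical subtype without AsPC1 replicate 3, AsPC1-R replicate 3, BxPC3 replicate 1 or BxPC3 replicate 3 (adjusted p = 0.0608, 0.0583, 0.0790 and 0.0788). The same held for endothelial markers without the first 3 of these arrays (0.112, 0.0839 and 0.0790) and for Fanconi anaemia without AsPC1 replicate 3, BxPC3 replicate 1 or BxPC3-R replicate 3 (0.107, 0.0537 and 0.0523). Mucins lost theirs without AsPC1 replicate 3 or BxPC3-R replicate 3 (0.0693 and 0.0550) and p53 targets without AsPC1 replicate 2 (0.0509). With dim genes left out, the classical subtype, mucins and p53 targets lost theirs (0.124, 0.0985 and 0.124), as did p53 targets with renewed normalization (0.0690) and the classical subtype with centred arrays (0.0796). Fibroblast markers differed without BxPC3 replicate 2 or BxPC3-R replicate 3 (0.0340 and 0.0321) and ribosomal proteins without AsPC1 replicate 2 (0.0270), but not with all arrays (0.0598 and 0.245).

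For 126 named genes, limma's test of the difference was passed with adjusted p values up to 0.0496, and the differences below are in the same unit and direction. Some were named by the rule through other comparisons, and the histone genes H4C8 and H2BC12 after their values were seen. With the higher change in AsPC1-R, and all 4 groups above 6.22 (the reading of the deleted CDKN2A in BxPC3), there were CXCL5 7.12, PI3 6.61, DUOX2 5.91, SLFN5 5.68, KYNU 5.62, IFI27 4.03, UCA1 3.94, AKR1C2 3.49, AKR1C1 3.16, TGFB2 3.11, ALDH3A1 3.06, HEXA 2.61 and TNFSF10 2.51. Further down the order stood PSMB9 2.43, SAMD9L 2.41, IFITM1 2.23, IFIT2 2.17, CFLAR 2.10, EGLN3 2.07, GCLC 2.06, ACTA2 2.05, SLC7A11 2.03, ME1 2.02, PSMB8 1.80, STAT3 1.78 and FAM83A 1.67. These were followed by ABCC3 1.64, B2M 1.57, PMAIP1 1.55, PLK2 1.53, H2BC12 1.52, GPX2 1.51, ALDH1A1 1.45, HLA-DMA 1.44, ALDOC 1.29, H4C8 1.26, MUC13 1.08, SLC31A2 1.08 and MUC2 1.00. The smallest of them were TXNIP 0.95, GCLM 0.90, TMEM205 0.87, CDKN1A 0.83, CCN2 0.79, XBP1 0.74, ABCC5 0.72, ATOX1 0.59, INSIG1 0.57 and ABCC2 0.56. ALDH1A1 read 8.25 on BxPC3 replicate 2, the array that stood apart, against 6.93 and 6.67 on the other BxPC3 arrays. That array raises the difference given for ALDH1A1. With the lower change in AsPC1-R, and all groups above that level, there were SYTL5 -3.96, HAS2 -3.65, HPGD -2.74, H4C4 -2.26, VIM -2.06, MYB -1.74, KITLG -1.62 and EEA1 -1.58. To these can be added DKK1 -1.37, AGR2 -1.33, CDS1 -1.33, GLMN -1.25, POLA1 -1.01, LIG1 -0.94, ORC1 -0.91 and CENPE -0.90. The smallest were NUF2 -0.90, FOXM1 -0.85, XRCC2 -0.84, CCNE2 -0.72, EGR1 -0.60, FOS -0.59, STARD4 -0.56 and CENPF -0.49. A group mean at or under that level makes the size uncertain for 53 of the genes. Where this held for 1 or more groups, but for no line as a whole, the values were SAA2 10.31, SAA1 8.83, CCL20 6.93, C3 6.85, SLC6A14 5.74, CST1 5.43, ANKRD1 4.83, CXCL10 4.78, AKR1B10 4.59 and SCEL 4.15. Lesser ones were VNN1 3.99, CXCL11 3.43, IFI44L 2.51, MAL2 2.01, CNN3 2.0, PECAM1 1.89, CD24 1.82, ABCC4 0.99 and IL1RAPL2 0.79. Negative ones were LUM -2.56, PAG1 -2.37, PTPRR -2.15, H2BC10 -1.83 and BMP4 -1.38. For 29 of these 53 both groups of a line lay there, so the change of that line is not shown to stand above background. The values of these were HLA-DPA1 5.33, TNIP3 4.49, C1S 4.01, S100A8 3.17, SPRR2A 3.01, TRIM22 2.64, CDH5 2.51 and FYB1 1.75. Next to them came HLA-DPB1 1.69, TEK 1.58, PLOD2 1.41, FN1 1.09, MUC16 1.00, CDKN2A 0.70 and ATP7B 0.65. With a negative sign stood FABP4 -3.40, CDH6 -2.91, RGS4 -2.76, PIK3C2G -2.47, RERG -2.38, IGFBP5 -2.14, GPA33 -2.12, MYO1A -1.76, CD36 -1.44, CDH2 -1.40, PALMD -1.21, REG4 -1.09, LEF1 -0.98 and LDHB -0.74. For CDKN2A, deleted in BxPC3, the change in BxPC3-R is a reading of background. Other probe sets of the same genes gave AKR1C1 1.81, CFLAR 0.86, FYB1 1.30, HLA-DPB1 0.88 and 1.91, PECAM1 0.58 and SAA2 5.35.

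Inflammatory and interferon genes were higher in AsPC1-R and lower in BxPC3-R, and 37 of the 71 measured members of both lists did both, though in BxPC3-R 17 of 39 interferon-stimulated genes fell and the list did not pass with an estimated correlation (adjusted p = 0.0786). Cells of BxPC3 mixed into the AsPC1-R cultures would need a median share of 39.0% by 43 of those genes (range 0.18% to 560.2%), but 19 of the 20 most abundant BxPC3 transcripts that are dim in AsPC1 lay more than 1 (log2) below the level this share would bring, and LDHB read 4.11 in AsPC1-R against 13.01 in BxPC3. Cells of AsPC1 mixed into the BxPC3-R cultures would need a median share of 73.2% by 32 of them, but 20 of 20 abundant AsPC1 transcripts lay below their predicted level, with CDH17 at 4.21 against a prediction of 12.83. An exchange of the parental and resistant labels for all arrays of 1 line cannot be told apart from a true opposition, since the correlation of the lines' changes across genes, -0.255, lies between the values that would decide it. A different state of the derivatives, which were kept at different cisplatin concentrations, also stays open and was not tested.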

How the results depend on the processing

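No called change of a list or of a gene taken by the naming rule reversed under the alternatives run for it, and the cause of a change in a count was not tested unless stated. A test against a 1.5-fold change, stricter by construction, called 398 genes in AsPC1-R, 396 in BxPC3-R, 933 for the difference between the lines and 2311 between the parental lines, and 7 genes changed the same way and 75 in opposite ways. An adjusted p under 0.01, also stricter, gave 2279, 2495 and 2998 genes for the first 3, 185 the same way and 549 in opposite ways. With array weights, BxPC3-R had 6356 genes, and 672 went the same way and 1525 in opposite ways; the weights ran from 0.351 for AsPC1 replicate 2 to 3.732 for BxPC3 replicate 3. With an estimated correlation, 11 lists passed in AsPC1-R, 5 in BxPC3-R and 7 for the difference, and 0 windows in either derivative by camera (42 and 39 at an unadjusted p under 0.05). The counts under all other alternatives stayed within 1.5 times. With 1 array left out, the counts ran from 2869 to 4246 in AsPC1-R, 2970 to 4181 in BxPC3-R, 3961 to 5296 for the difference, 7729 to 9899 for the parental lines, 313 to 471 the same way and 762 to 1047 in opposite ways, and the lists from 16 to 20, 14 to 18 and 15 to 20. At least 2-fold, they ran from 425 to 451 in AsPC1-R and from 425 to 458 in BxPC3-R. With replicate number as a block, 3553 and 3661 genes changed in AsPC1-R and BxPC3-R; the numbers do not pair the arrays, since deviations of same-numbered arrays from their group means correlated across genes at -0.026, -0.239 and -0.203 in the AsPC1 line and 0.171, -0.088 and 0.078 in the BxPC3 line. LYZ in BxPC3-R, not called with all arrays (limma adjusted p = 0.325), read -0.89 with all arrays and 0.12 without BxPC3 replicate 2. Windows of 25 genes gave 52 and 51 passes. Centring each array moved the share of rises among the genes called from 46.9% to 56.7% in BxPC3-R and from 57.3% to 53.7% in AsPC1-R, with shifts of the median under 0.1. Of 353 results for named genes, 168 lost their call against a 1.5-fold change, 22 with only the groups compared (319 stayed the same there, and the rest were not run), 7 with the block, 5 with array weights, 4 with centring, 4 with renewed normalization, 1 with the mean over probe sets and 0 with trend and robust, and 170 of 4236 lost it and 1 gained it when 1 array was left out. Of 102 results for single lists, 31 lost their call with an estimated correlation, 9 with dim genes left out (81 stayed the same there, and the rest were not run), 2 with centring, 2 with renewed normalization and 1 with the block, and with 1 array left out 28 of 1224 lost and 11 gained it. Background was not measured here, so how far it limits the genes whose group means stay under 6.554 (log2) was not tested.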

Other observations

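The tests of explanations in this part were chosen after the results were seen, and no biological explanation was tested for the patterns. The difference between the lines that camera tested for lists can also be read in another way, with no further test. This sets the distance between the derivatives beside that between the parental lines. BxPC3 stood above AsPC1 by a median of 1.90 (log2) over interferon-stimulated genes and 1.44 over NF-kB and inflammatory genes, while BxPC3-R stood above AsPC1-R by 0.18 over the first and at -0.61 over the second. For NRF2 targets and antigen presentation the medians went from 0.05 and 0.58 between the parental lines to -0.91 and -0.59 between the derivatives. By limma, 9316 genes differed between the parental lines and 7971 between the derivatives, 2040 and 1922 of them at least 2-fold.

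Histone genes, a group chosen by symbol after the values were seen, were not tested as a list. Of 60 measured histone genes, 31 fell and 5 rose in AsPC1-R, with a median of -0.47, and 16 rose and 2 fell in BxPC3-R, with a median of 0.17, while the others did not pass. The histone genes H2BC10 and H4C4 stood at -1.57 and -1.51 in AsPC1-R and at 0.26 and 0.75 in BxPC3-R. H4C8 and H2BC12 went the other way in AsPC1-R, at 1.49 and 1.36, and H4C9 in BxPC3-R, at -1.09. Limma's test of the difference was passed by 28 of the 60 with a lower and 4 with a higher change in AsPC1-R. Centring the arrays moves the median of all genes by -0.009 in AsPC1-R and 0.047 in BxPC3-R, less than these medians. Histone genes are similar in sequence, and 2 of the 60 had values identical to each other.

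Genes of chromosome 12 were lower in AsPC1-R and higher in BxPC3-R, untested as a difference, as to a smaller extent were those of chromosome 1 (medians -0.091 and 0.082), while chromosomes 3, 15 and 17 showed the reverse (0.027 and -0.021, 0.205 and -0.046, 0.143 and -0.037). A few strongly changed genes are an unlikely cause, since 69.6% of expressed genes were lower in AsPC1-R and 78.7% higher in BxPC3-R. Random lists of genes matched in expression level, drawn over all chromosomes, had ranges of -0.043 to 0.022 and -0.016 to 0.042. The medians of chromosome 12, -0.134 and 0.225, lay outside them, so level alone did not give such medians in these lists. But 7 of 23 chromosomes in AsPC1-R and 11 of 23 in BxPC3-R, chromosome 12 included, lay outside their ranges. The ranges do not allow for neighbouring genes varying together, so lying outside does not single out chromosome 12. A change along the whole chromosome, such as a gain of a copy, may underlie the shift in BxPC3-R, where 20 of 20 windows had medians above that of all expressed genes. Copy number was not measured. Chromosome 12 was picked after its shift was seen and no spread of this count is known, so the count does not show such a gain. In AsPC1-R 14 of 20 windows lay below the median of all expressed genes. This does not decide between the whole chromosome and a part, for the same lack of a known spread. There 10 neighbouring windows from ARID2 to ATP2A2 passed camera with the preset correlation. With an estimated one, 0 of the 369 windows passed in either derivative (42 and 39 at an unadjusted p under 0.05). A change of the whole chromosome or of part of it stays open in AsPC1-R.

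On BxPC3 replicate 2, the transcripts by which AsPC1 exceeds BxPC3-R most were higher than on the other BxPC3 arrays, 50 of 50, against 0 on either of the others. On the arrays of the other groups, 7 to 27 of the 50 corresponding transcripts of the opposite line were highest. AsPC1 RNA in the sample of BxPC3 replicate 2 may account for this, with a median implied share of 2.22% (0.34% to 6.72%). A higher reading of genes in general was not seen on that array, since 10497 genes near equal in AsPC1 and BxPC3-R had a median excess of -0.006. These genes came from the whole range of levels that the 50 transcripts had on the other BxPC3 arrays. They were not matched one by one, so a higher reading of the dimmest genes alone was not tested. Of the 50 transcripts, 17 were called lower in BxPC3-R with all arrays and 18 without replicate 2, where CDH17 went from -1.95 to -0.53 (limma adjusted p = 0.0458) and VNN1 from -3.66 to -3.33 (1.41e-09). The 50 were chosen by the excess of AsPC1 over BxPC3-R, which favours low levels in BxPC3-R. These 2 counts therefore do not show whether replicate 2 affects the calls.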
